A study of Mus musculus with 8 samples.

How the data were processed

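Total RNA of heart ventricles from 8 banded mice, 4 labelled transgenic for CHF1/Hey2 and 4 wild type, was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per mouse, per the labels' protocols. The authors deposited log2 expression values, and the submitters' processing notes name GCRMA, a method that corrects the background of each probe by its base composition, normalizes the arrays by quantiles and summarizes the probes of a probe set. Its version is not given in the sources used here. The deposited log2 values lay between 0.84 and 16.11, with array medians between 3.33 and 3.43. GCRMA pulls probe sets without signal to a common low level, which makes differences near that level hard to read. No counts exist for arrays, and the number of arrays limits the precision.

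The table holds 45101 probe sets, of which 64 are controls. The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and no row for 9211. Symbols were updated through the Entrez identifier, which matched 34754 probe sets and changed 0 symbols. Probe sets with several symbols or none were left out of the gene tests. Probe sets had to exceed a log2 value of 5 in at least 4 of the 8 arrays, whatever their group, and 17876 did. For each gene the probe set with the highest mean over the 8 arrays was kept, which left 9607 genes. No genome was used here and no coordinates are given.

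Groups were taken from the sample titles. The comparison was transgenic minus wild type, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) over all 8 arrays without a block, with Benjamini-Hochberg adjustment at 0.05. Hey2 was also tested with an exact two-sided permutation test of its group means. Shifts of gene lists were tested with camera of limma at a preset correlation of 0.01, over lists with at least 5 measured members, with Benjamini-Hochberg adjustment at 0.05 over the lists. The 34 lists hold 879 genes, of which 677 were measured, and 29 lists were tested. The lists of lymphocytes, neutrophils and mast cells, erythroid cells, skeletal muscle and of epicardial and neural cells had 2, 3, 3, 3 and 4 measured members and were not tested. The lists, the test, the filter, the alternatives and the rule for named genes were chosen before the data were examined. The rule named Hey2, the 10 genes with the largest change in each direction among genes that passed and whose groups did not overlap, filled up by the smallest p as values that did not pass, a panel of 11 genes, and up to 4 members with the smallest p of each list described, with clone identifiers left out of the ranking by p.

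The steps were tested on simulated data with the spread of each gene in these arrays. With all 8 arrays and 9607 genes, 33 of 100 genes changed by 1 log2 unit and 79 of 100 changed by 2 were recovered. Without transgenic replicate 2 the recovered numbers were 69 and 96 of 100. The simulated noise was independent between genes and equally wide in every array, whereas the real spread lay largely in single arrays. These numbers are therefore not the power of the real comparison. Genes simulated without a change gave 3 calls with all 8 arrays and 12 without transgenic replicate 2. A list shifted by 0.5 was called in both simulations, and 0 of the other lists were. This list result does not show that the list test is specific in the real arrays. There, the 8 arrays were also split into 2 groups of equal size in every way. Of these 35 splits, 24, the real one included, passed at least the 5 lists of the real split, and the highest other count was 12.

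Alternatives changed the filter (none, above 7 in at least 4 arrays, or a mean above 5), the scaling (quantile normalization or median centring on top of the deposited values), the model (trend with a robust prior, array weights, a replicate block), the probe set rule (every probe set, the mean of a gene's probe sets, or no probe sets with the suffix _x_at or _s_at), the test (Welch's test for genes; camera with an estimated correlation, camera on ranks and fry for lists), the threshold (0.1, or an added log2 change of at least 1), and left out each array in turn. Leaving out transgenic replicates 2 and 3 together, and the estimated correlation without transgenic replicate 2 and without both, were added after seeing the data.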

Results

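Ventricular transcript levels were measured in 8 male FVB mice, an inbred strain, 1 week after ascending aortic banding, an operation that narrows the aorta close to the heart so that the left ventricle contracts against a higher pressure. Of these mice, 4 carried a transgene for CHF1/Hey2, a transcriptional repressor of the hairy-related family, driven in heart muscle by the mlc2v promoter, and 4 were wild type. The mice were 8 to 12 weeks old, and every heart was banded. Hearts without banding were not analysed here, so the response to banding itself has no comparison. Each mouse gave 1 Affymetrix Mouse Genome 430 2.0 array with 45101 probe sets, and between 16984 and 18028 of them lay above a log2 value of 5 in an array. Arrays give no read depth, and their number limits the precision.

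The arrays did not resemble each other equally. Across the 9607 genes tested, transgenic replicate 2 correlated with the other 7 arrays at r between 0.788 and 0.840, and 3572 genes (37.2%) lay over 2-fold from the median of the other arrays. In transgenic replicate 3 this held for 891 genes (9.27%), of which 670 were lower. In each of the remaining 6 arrays the number was between 72 and 149, and the 15 correlations among these 6 arrays were between 0.977 and 0.992. These correlations are across genes, which are not independent replicates.

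**Figure D1:**
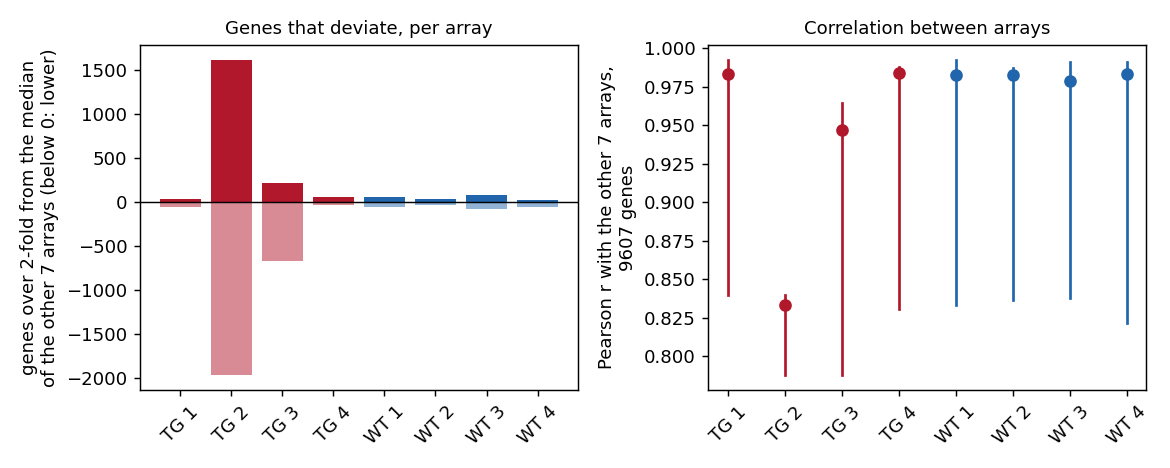
Left, number of genes over 2-fold from the median of the other 7 arrays in each array, with higher genes above 0 and lower genes below. Right, Pearson correlation of each array with the other 7 arrays over 9607 genes, as the median (point) and the range (line), with transgenic arrays (TG) in red and wild-type arrays (WT) in blue. Transgenic replicate 2 has 3572 such genes and transgenic replicate 3 has 891, against at most 149 in any other array.

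Hey2 itself was not higher in the arrays labelled transgenic. Its only probe set on this array gave log2 values of 5.87, 5.70, 6.26 and 6.02 in transgenic replicates 1 to 4 and of 5.89, 5.96, 5.68 and 6.76 in wild-type replicates 1 to 4. The group means were 5.96 ± 0.24 and 6.07 ± 0.47 (SD, n = 4 each), a difference of -0.11 (95% confidence interval -0.70 to 0.47) that was smaller than the spread between mice (exact two-sided permutation p = 0.771, where the smallest possible p is 0.0286). Without wild-type replicate 4 the difference was 0.12, so its sign rested on that array. The labels do not give the sequence of the construct, so whether this probe set reads the transgene is not known, and Hey2 could not be used to check the labels. The groups are therefore called arrays labelled transgenic and wild type.

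The comparison of banded transgenic with banded wild-type hearts addressed how CHF1/Hey2 in heart muscle bears on gene expression under pressure load. Genes of the extracellular matrix and of the fetal and hypertrophic program were lower as groups in the arrays labelled transgenic, and genes of the respiratory chain, of fatty acid oxidation and of antioxidant defence were higher as groups, but none of these shifts held with an estimated correlation between genes (adjusted p = 0.80 with an estimated correlation for each of the 5 groups). The matrix median lay at -2.13 from the wild-type mean in transgenic replicate 3 but at 0.59 in replicate 2. Without transgenic replicate 3, 0 lists passed, and the medians of the matrix and hypertrophy lists were 0.06 and 0.04. No single gene passed. With limma and Benjamini-Hochberg adjustment at 0.05, 0 genes were higher and 0 were lower among 9607, and the smallest adjusted p was 0.813. At an unadjusted limma p under 0.05 there were 153 genes (1.59%), 117 higher and 36 lower, and an unequal-variance test run gene by gene with the same adjustment also passed 0 genes, with 144 at an unadjusted p under 0.05. The median 95% confidence interval of a gene reached 0.606 on the log2 scale to either side of its difference. Without transgenic replicate 2 it reached 0.390, and again 0 genes passed, with 232 at an unadjusted p under 0.05.

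Genes by which myocyte stress is commonly read differed between the 2 groups by less than the SD of the arrays labelled transgenic. Transgenic replicate 3 held the lowest values of several. The differences of Nppa, Myh7 and Acta1 were larger than their wild-type SDs of 0.25, 0.44 and 0.16. Nppb, which encodes B-type natriuretic peptide, had means of 14.14 ± 0.39 and 14.20 ± 0.15 in arrays labelled transgenic and wild type (SD, n = 4 each). Acta1, skeletal alpha-actin, had 14.61 ± 0.34 and 14.79 ± 0.16. Nppa, atrial natriuretic peptide, was 12.96 in transgenic replicate 3 and at least 15.02 in the other 3 arrays labelled transgenic, with a group difference of -0.44 (SE 0.476). Myh7, the slow myosin heavy chain, was 12.14 in that array and at least 14.06 in the other 3, with a difference of -0.54 (SE 0.510). Without transgenic replicates 2 and 3 the differences of Nppa and Myh7 were 0.13 and 0.08. Myh6, the adult myosin heavy chain of the mouse ventricle, differed by -0.01 (SE 0.148), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.04 (SE 0.142). Without transgenic replicate 2 these 2 genes differed by 0.07 and 0.09. The limma adjusted p of each gene of this paragraph was 0.813 or more. Myh6 held the highest value of every array except transgenic replicate 2. Normalization by quantiles keeps the top of the scale nearly alike across arrays, so a difference near 0 says little about Myh6.

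Gata4, a cardiac transcription factor, differed by 0.49 (SE 0.282; 0.32 without wild-type replicate 3), and Hey1, a relative of Hey2, by 0.59 (SE 0.245), with Hey1 at 7.33 or more in transgenic replicates 2, 3 and 4 but at 6.61 in replicate 1. Myl7, the atrial regulatory light chain of myosin, had means of 10.83 ± 0.33 and 10.12 ± 0.25 (SD, n = 4 each), a difference of 0.71 (SE 0.217). It did not pass (limma adjusted p = 0.813; exact permutation p = 0.0571), and transgenic replicate 1, at 10.42, lay below wild-type replicate 1, at 10.47. The matrix genes Col1a1, the alpha 1 chain of type I collagen, and Postn, periostin, differed by -1.02 (SE 0.763) and -1.35 (SE 0.675), and both were lowest in transgenic replicate 3, at 10.44 and 11.38. The corresponding wild-type means were 14.10 ± 0.20 and 14.89 ± 0.20. Without transgenic replicates 2 and 3 the differences of Col1a1 and Postn were -0.27 and -0.18.

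**Figure D2:**
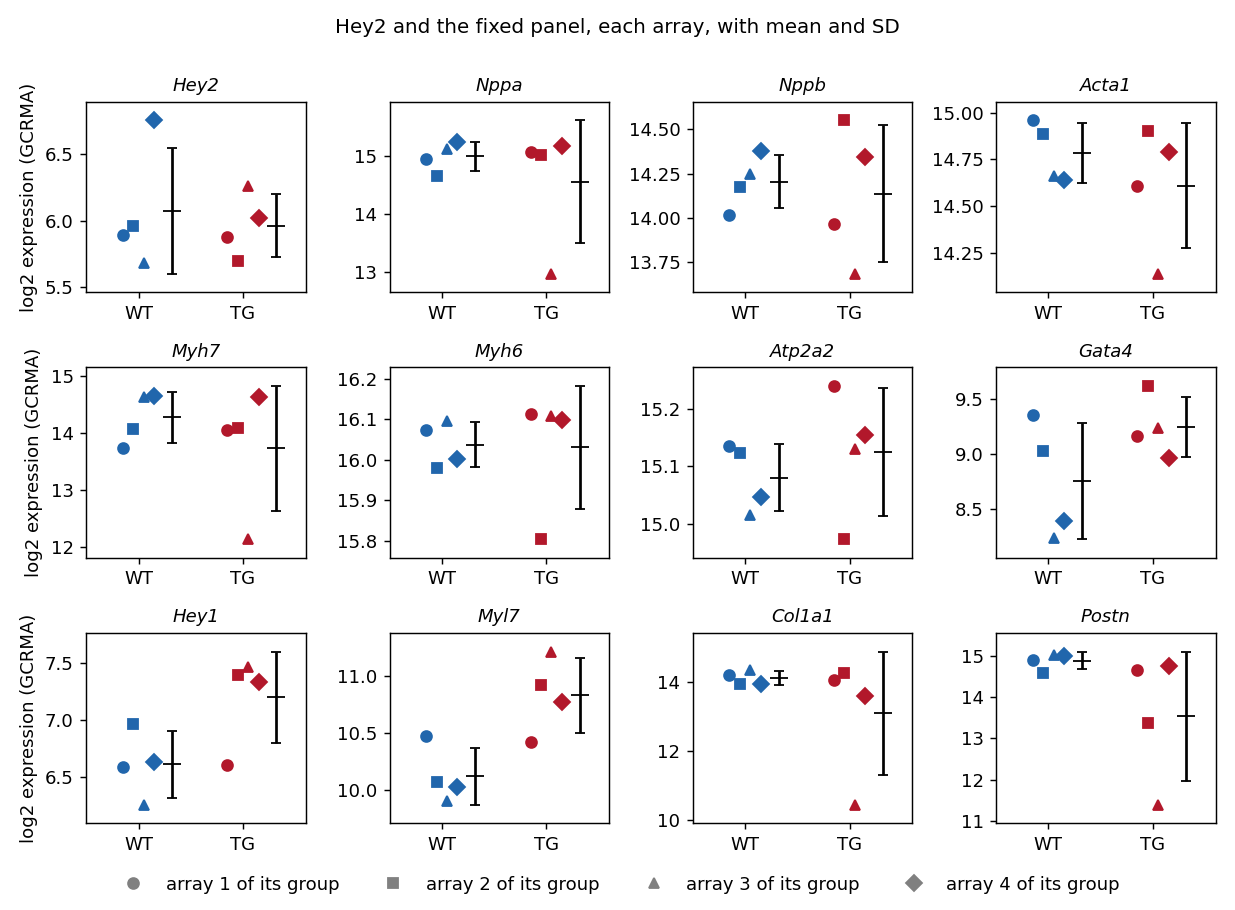
Log2 expression (GCRMA) of Hey2 and of the panel of 11 genes, in each of the 8 arrays, with the mean and SD of each group (n = 4) beside the points; each panel has its own vertical axis, and the same symbol in both groups marks the same replicate number, which was not taken to pair mice. Transgenic replicate 3 (red triangle) lies lowest for Nppa, Myh7, Col1a1 and Postn.

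Since no gene passed, the 10 genes with the smallest p in each direction are given as values that did not pass. Inmt, which encodes a methyltransferase of indole amines, had means of 5.52 ± 0.19 in arrays labelled transgenic and 4.51 ± 0.11 in wild type (SD, n = 4 each), a difference of 1.01 (limma adjusted p = 0.813; exact permutation p = 0.0286). Its 4 values in arrays labelled transgenic all lay above its 4 wild-type values, but all 4 wild-type values lay below the level of 5 that the filter required, where differences are hard to read. Cds1 lay below this level in 3 wild-type arrays, and Rnf152 in 4, Kcnj15 in 3 and Spire1 in 2 arrays labelled transgenic. The other genes on the higher side were Erbb3, a neuregulin receptor, at 0.70, Cds1 at 1.21, Bend3 at 0.53, Igsf1 at 0.81, Myl7 at 0.71, Pcp4l1 at 1.06, Twnk, the helicase of mitochondrial DNA, at 0.49, Rhbdd3 at 0.62, and Kcnh2, the pore subunit of the rapid delayed rectifier potassium channel, at 0.83. On the lower side were Rnf152 at -1.04, Klhdc8b at -0.74, Kcnj15, an inward rectifier potassium channel, at -1.68, Tm6sf1 at -0.53, Spire1, an actin nucleator, at -0.82, Stk17b at -0.91, Trabd2b at -0.63, Daam2 at -0.48, Zdhhc20, a palmitoyltransferase, at -0.84, and Resf1 at -1.01. Zdhhc20 and Resf1 differed by -0.56 and -0.65 without transgenic replicate 2. The 2 groups did not overlap for 238 genes (2.48%), where chance gives 2.86%. With limma's array weights, Inmt passed (adjusted p = 0.0373, against 0.555 to 1.00 over its other alternatives).

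Matrix genes were lower as a group in the arrays labelled transgenic. Of 39 measured members of the extracellular matrix and fibrosis list, 37 had a lower mean and 2 a higher one, with a median difference of -0.51 (limma camera, adjusted p = 1.71e-07; adjusted p = 0.80 with an estimated correlation). Lox, the enzyme that cross-links collagen, differed by -1.95, Col8a1 by -1.45, Postn by -1.35 and Pdgfra, a receptor of fibroblasts, by -0.37. Without transgenic replicate 3, Lox, Col8a1 and Postn differed by -1.12, -0.84 and -0.63. These remaining differences rested in large part on transgenic replicate 2, where they lay at -2.30, -2.09 and -1.52 from the wild-type mean. Without both replicates 2 and 3, Postn differed by -0.18. No member passed, with 0 over all genes and 0 adjusted over the list alone, and 1 member had an unadjusted limma p under 0.05. The list's median lay at -2.13 from the wild-type mean in transgenic replicate 3, at 0.59 in replicate 2, at -0.04 in replicate 1 and at -0.16 in replicate 4. Without transgenic replicate 3 the median difference was 0.06 while the test still pointed lower (adjusted p = 0.660). Without both replicates 2 and 3, an alternative chosen after seeing the data, it was -0.10 (adjusted p = 1.51e-06; adjusted p = 0.986 with an estimated correlation).

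The hypertrophy and fetal program list had 17 of 20 measured members lower, with a median difference of -0.19 (limma camera, adjusted p = 0.0481; adjusted p = 0.80 with an estimated correlation). Actn1, an alpha-actinin, differed by -0.62, Enah by -0.49, Myh7 by -0.54 and Acot1, an acyl-CoA thioesterase, by 0.52. Without transgenic replicate 2, at 11.47 for Enah against at least 12.47 in the other 3 arrays labelled transgenic, Enah differed by -0.16, and without transgenic replicate 3 Actn1, Myh7 and Acot1 differed by -0.30, -0.01 and 0.20. No member passed over all genes or adjusted over the list alone, and 0 had an unadjusted limma p under 0.05. The median was -0.64 in transgenic replicate 3 and between -0.20 and 0.18 in the other 3 arrays labelled transgenic. Without transgenic replicate 3 it was 0.04, opposite in sign to the test (adjusted p = 0.671), and without both replicates 2 and 3 it was 0.02 (adjusted p = 0.136). Without transgenic replicate 1 and without wild-type replicate 3 the call was lost as well (adjusted p = 0.243 and 0.195). Of the groups that were not called, the sarcomere list had 12 of 23 members lower, with a median of -0.01 (0.04 without transgenic replicate 2), and Nexn, at -0.93, was 9.54 in transgenic replicate 2 and at least 13.37 in the other 3 arrays labelled transgenic, with a difference of 0.07 without that array. The calcium handling list had a median of -0.05, with -0.61 in transgenic replicate 2, and without that array the median was 0.11, with 13 of 17 members higher and the test pointing higher.

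Respiratory chain genes were higher in 44 of 52 members, with a median difference of 0.12 (limma camera, adjusted p = 0.0481, and 0.80 with an estimated correlation). Genes as a whole also lay slightly higher. The median difference over all 9607 genes was 0.06, or 0.05 without transgenic replicates 2 and 3. Fatty acid oxidation genes were higher in 20 of 26 members, with a median of 0.20 (limma camera, adjusted p = 0.0494; adjusted p = 0.80 with an estimated correlation). Among them Slc27a1, a fatty acid transporter, differed by 0.60, Mlycd, malonyl-CoA decarboxylase, by 0.65, Slc25a20, the carnitine carrier of mitochondria, by 0.47 and Cpt2 by 0.42. Slc27a1 and Mlycd lay at 1.02 and 1.09 from the wild-type mean in transgenic replicate 3 and at 0.78 and 1.05 in replicate 2. Of the respiratory chain, Atp5e differed by 0.32, Atp5g2 by 0.41, Ndufa8 by 0.25 and Uqcrq by 0.21. Slc25a20 and Atp5g2 differed by 0.28 and 0.26 without transgenic replicate 2, and without replicate 3 Cpt2 differed by 0.25. No member of either list passed over all genes or adjusted over the list alone, and 0 and 2 members had an unadjusted limma p under 0.05. In transgenic replicate 3 the medians of the respiratory chain and fatty acid oxidation lists lay at 0.29 and 0.61, against at most 0.12 and 0.22 in the other 3 arrays labelled transgenic. Without transgenic replicate 3 the median differences were 0.06 and 0.08 (limma camera, adjusted p = 0.972 each), and without replicate 4 that of fatty acid oxidation was 0.33. Without both replicates 2 and 3 the medians were 0.04 and 0.02 (adjusted p = 0.980 each), with the test of fatty acid oxidation pointing lower. Both calls were also lost without transgenic replicate 1 (adjusted p = 0.243 each) and without wild-type replicate 3 (adjusted p = 0.306 and 0.247), and that of fatty acid oxidation without wild-type replicate 1 (adjusted p = 0.102).

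Antioxidant genes were higher in 21 of 26 members, with a median difference of 0.19 (limma camera, adjusted p = 0.0494; adjusted p = 0.80 with an estimated correlation). Gstm1, a glutathione transferase, differed by 0.58, Txnrd2 and Txn2, of the mitochondrial thioredoxin system, by 0.54 and 0.44, and Mgst1 by 0.36. Txnrd2 differed by 0.31 without transgenic replicate 2. No member passed over all genes or adjusted over the list alone, and 1 had an unadjusted limma p under 0.05. The median lay at 0.56 in transgenic replicate 2 and at 0.12, 0.16 and 0.19 in replicates 1, 3 and 4. The median difference was 0.11 without transgenic replicate 2 and 0.31 without replicate 3. The call was lost without any single array other than wild-type replicate 1 (adjusted p between 0.0578 and 0.242, with 0.170 without transgenic replicate 2 and 0.0628 without replicate 3), while without both replicates 2 and 3 the list was higher (adjusted p = 0.0406; adjusted p = 0.986 with an estimated correlation). With each array centred on its median, the matrix list was the only group of the 5 that passed, and with quantile normalization the matrix and hypertrophy lists did.

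The remaining 24 lists did not pass with camera (adjusted p between 0.113 and 0.932). In each of the 24, and also in each of the 5 that passed, the median moved by over 1.5 times or turned its sign when some single array was left out. Among lists on metabolism, the citric acid cycle had a median of 0.11 (limma camera, adjusted p = 0.444), the list of PGC-1, PPAR and ERR regulators a median of 0.19 and a mean of 0.01 (adjusted p = 0.484) and glycolysis a median of 0.11. Without transgenic replicate 3 the medians of the first 2 were 0.03 and -0.05, with both tests pointing lower, and that of glycolysis was 0.04 without transgenic replicate 2. Esrra and Esrrb, nuclear receptors that regulate mitochondrial genes, differed by 0.43 and 0.67. They lay at 0.69 and 1.23 from the wild-type mean in transgenic replicate 3 and at 0.69 and 0.94 in replicate 2. The Notch and Hey list had 12 of 17 members higher, with a median of 0.17, and without transgenic replicate 2 it had 9 higher, with a median of 0.02 and the test pointing lower. Mfng and Dll4 differed by 0.52 and 0.61, or by 0.20 and 0.33 without transgenic replicate 2. The list of cardiac transcription factors had a median of 0.21 (0.08 without wild-type replicate 3), with Tbx5 at 0.56, Irx4 at 0.45 and Nkx2-5 at 0.34. Without transgenic replicate 2, Tbx5 and Nkx2-5 were at 0.27 and 0.19, and without wild-type replicate 3 Irx4 was at 0.25. Ion channels had a median of 0.17 (0.07 without transgenic replicate 3), with Scn4b at 1.03, Kcnip2 at 0.26 and Kcnk3 at 0.20 (0.07 without transgenic replicate 3), and the atrial list a median of 0.13 (-0.07 without transgenic replicate 1), with Myl4 at 0.67 and Stard10 at 0.63. The IGF, PI3K and Akt list had a median of 0.07 but a mean of -0.05, with Igf1 at -1.18 and Akt2 at 0.47 (-0.55 and 0.26 without transgenic replicate 2), and the calcineurin and MAPK list a median of -0.04 (0.04 without that array). Translation had a median of 0.08 and proteolysis and autophagy 0.08, or 0.01 and -0.02 without transgenic replicate 2. The endoplasmic reticulum stress and heat shock list had -0.02 (0.06 without wild-type replicate 2) and apoptosis 0.04 (-0.08 without transgenic replicate 2), the last with a mean of -0.06 and Bcl2 at -1.11 (-0.70 without transgenic replicate 2).

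Lists of other cell types and of systemic programs differed between single arrays labelled transgenic. The macrophage list had a median difference of -0.03, made of 0.90 in transgenic replicate 2 and -1.06 in replicate 3, and its median was -0.27 without the first and 0.39 without the second. The endothelial list had 0.26, with 0.76 in transgenic replicate 2, and the interferon list 0.26, while without that array they had 0.07 and 0.01, with the interferon test pointing lower. Of the interferon list, Igtp and Psmb9 differed by 1.11 and 1.08, or by 0.60 and 0.55 without transgenic replicate 2. The median of the interferon list lay at 0.52, 1.18, -0.40 and 0.00 in transgenic replicates 1 to 4, and at 0.30 in wild-type replicate 1, the highest of the wild-type arrays. Without both replicates 2 and 3 this list was higher, with a median of 0.33 (limma camera, adjusted p = 6.31e-04; adjusted p = 0.986 with an estimated correlation). The adipocyte list had 0.22, the circadian list -0.16 and the cell cycle list -0.11, or 0.13, -0.04 and -0.26 without transgenic replicate 2, and the cell cycle list had 0.08 without replicate 3. Of this list, Mki67, a marker of proliferating cells, differed by -1.30 (SE 0.767), or by -0.76 without transgenic replicate 2 and -0.16 without both replicates 2 and 3. The smooth muscle, inflammation and immediate early lists had medians of 0.00, 0.04 and 0.02, while their tests pointed lower, and without transgenic replicate 2 the medians were -0.06, -0.07 and -0.23. Cxcl12, a chemokine of the inflammation list, differed by 0.59 (SE 0.237). Without transgenic replicate 2, 10 lists passed. These were 4 of the 5 described above, all but the antioxidant list, with the cell cycle, immediate early and macrophage lists, which were lower (limma camera, adjusted p = 4.36e-04, 1.88e-05 and 6.76e-04), and the citric acid cycle, ion channel and PGC-1, PPAR and ERR lists, which were higher (adjusted p = 0.00813, 0.0148 and 0.0346; adjusted p = 0.70 with an estimated correlation in each of the 10). Without both replicates 2 and 3, 7 lists passed. Besides the matrix, antioxidant and interferon lists, these were the cell cycle, immediate early, circadian and endoplasmic reticulum stress lists, all lower (limma camera, adjusted p = 0.0184, 1.26e-04, 0.0239 and 0.0184; adjusted p = 0.986 with an estimated correlation in each).

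**Figure D3:**
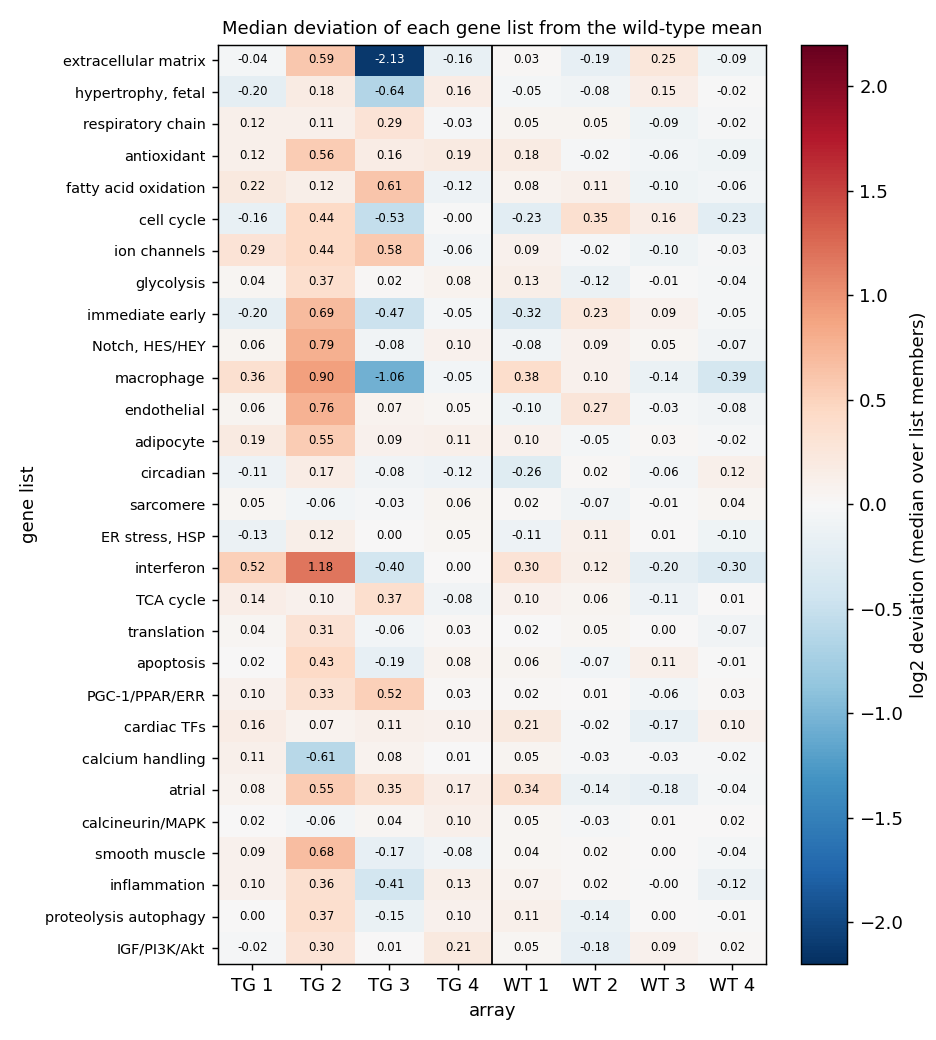
Median over the measured members of each of 29 gene lists of the log2 deviation from the wild-type mean, in each of the 8 arrays, on a colour scale from blue (lower) to red (higher). The column of transgenic replicate 3 holds the lowest value, -2.13 for the extracellular matrix, and that of transgenic replicate 2 the highest, 1.18 for the interferon list.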

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

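The tests of RNA degradation, of RNA from other cell types, of the fibroblast share, of pressure load, of exchanged labels and of the reading of the transgene were chosen only after the result was seen. An array counted as far from its group when its gap to the nearest of the other 3, divided by the range of the group, was above Dixon's 95% critical value for 4 values. Of 344 groups of 4 values tested, 25 passed this value, where about 17.2 would be expected by chance for unselected, normally distributed values. Many of the genes were chosen by a small p in these data, and the list medians share genes with them. The expected number is therefore only a guide. Of the 25, 13 had transgenic replicate 2 as the distant array, 2 had transgenic replicate 3 and 10 had another array. Where transgenic replicates 2 and 3 both deviate the ratio is smaller, so these counts can understate either array.

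In transgenic replicate 2 the ratio was 0.947 for Trabd2b (7.61), 0.949 for Myh6 (15.80), 0.832 for Scd1 (8.75), 0.859 for Camk2d (8.84) and 0.878 for Nr1d2 (9.41, with the nearest of the other 3 at 12.22). It was 0.880 for Mfng (7.54), 0.893 for Maml1 (9.22), 0.944 for Fbxo30 (6.03, nearest 8.40), 0.907 for Nexn (9.54, nearest 13.37) and 0.912 for Eif3a (10.08, nearest 12.56). For the list medians of calcium handling, the circadian clock and endothelial cells it was 0.867, 0.861 and 0.971 in that array. In transgenic replicate 3 the ratio was 0.934 for Nppa (12.96, nearest 15.02) and 0.934 for Actn1 (9.49, nearest 10.72). In transgenic replicate 1 it was 0.838 for Hey1 (6.61, nearest 7.33). Among the wild-type arrays the ratio was 0.853 for Inmt in replicate 4, 0.975 for Igsf1, 0.836 for Mcm4 and 0.869 for Acot1 in replicate 1, 0.844 for Pcp4l1 and 0.873 for Pfkm in replicate 3, and 0.991 for Idh3g in replicate 2. The list median of calcium handling had 0.883 in wild-type replicate 1, at 0.05, and the median correlation with the other arrays had 0.871 in wild-type replicate 3, at 0.978.

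Transgenic replicate 2 lay over 8-fold below the median of the other arrays for 318 genes, against at most 43 in any other array. The beta-actin controls gave no sign of RNA degraded from the 5 prime end. The 3 prime control exceeded the 5 prime control by 0.616 on the log2 scale, the lowest of the 8 arrays. The others had 0.784 to 1.21. These controls read a single abundant transcript, at 15.00 and 14.38 in this array. Normalization keeps the top of the scale nearly alike, so they say little about degradation of other transcripts, which stays open. Added RNA of other cell types lowers no gene much more than it lowers genes of myocytes, yet 925 genes lay over 2 log2 units below the median of the sarcomere list; transgenic replicate 3 also had 123 and the other 6 arrays at most 6, a ratio short of the 10 times that the test required, so it stays open. Signal that depends on the probe set rather than on the gene is not excluded, since the deviations of a gene's 2 highest probe sets correlated at r = 0.756 across 4049 genes, between the values of 0.5 and 0.8 that were to decide, but of 504 genes over 4-fold off by the first probe set the second lay over 2-fold off in the same direction in 77.8% and within 0.5 log2 units in 11.7%, which goes against it for most of these genes. These cannot be told apart from each other or from a property of this mouse, and no biological explanation was tested.

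Transgenic replicate 3 lay below all 6 arrays other than transgenic replicate 2 for 38 of 39 matrix genes and 16 of 21 macrophage genes, and above all 6 for 21 of 26 fatty acid oxidation genes. The beta-actin 3 prime to 5 prime difference was 1.02, within the range of the others. As in transgenic replicate 2, these controls say little about degradation of other transcripts. Signal that depends on the probe set is argued against by a correlation of r = 0.833 across 4049 genes. An equal loss of all fibroblasts would lower their markers and the matrix genes by about as much. The 10 markers of resident fibroblasts (5 of them also in the matrix list) had a median deviation of -0.58 (-1.76 to 0.33). For 16 load-responsive genes of the matrix list it was -3.35 (-5.01 to -1.90), a gap of 2.77, or 1.59 with all 34 matrix list members that are no such marker. The matrix genes are part of the pattern and the test was chosen after it was seen, so the choice partly sets this gap. Fewer of only those fibroblasts that make these matrix genes would also leave such a gap, so a smaller share of fibroblasts is left open. Less pressure load, or a smaller response to it in this mouse, stays open. The median of Nppa, Nppb, Acta1, Myh7 and Ankrd1 lay at -0.59, but these genes are part of the pattern and give no separate evidence, and load was not measured in the values used here, so a weaker band cannot be told apart from an effect of the transgene in this mouse.

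Hey2 was not higher in the arrays labelled transgenic. The largest gap between neighbouring Hey2 values of the 8 arrays was 0.50 on the log2 scale, so no separate high group existed under either label. A probe set that does not read the transgene could leave the difference at -0.11. It cannot be told apart from a low level of the transgene or from labels exchanged between the groups, since neither the construct nor the probe sequences were used here and without the transgene's signal no high group can appear.

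Other splits of the arrays were set beside the real one. The real split of the 8 arrays into 4 and 4 passed 0 genes with limma, a count that all 35 splits reach, so it decides nothing about chance, and the highest other count was 0. For genes at an unadjusted p under 0.05, 17 of the 35 splits gave as many as the real 153, and the highest other was 747. For genes whose groups did not overlap, 16 of 35 gave as many as the real 238, and the highest other was 844. For lists shifted, 24 of 35 gave at least the real 5, and the highest other was 12; without transgenic replicate 2, 14 of 35 splits into 3 and 4 gave at least the real 10, and the highest other was 15. Chance can be excluded for none of these 4 counts. The split with 747 genes set transgenic replicates 1, 2 and 3 and wild-type replicate 2 against the rest.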

How the results depend on the processing

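Leaving out transgenic replicates 2 and 3 together, and the estimated correlation without transgenic replicate 2 and without both, were chosen after seeing the data. The count of 0 genes lower held under all alternatives run. That of 0 genes higher held under all but limma's array weights, which passed 1 gene, Inmt, with 1529 genes at an unadjusted limma p under 0.05. These weights were 6.62 for transgenic replicate 1 and 0.0519 for transgenic replicate 2. Leaving out each array in turn gave 0 to 0 genes in either direction (limma, 34 to 541 at an unadjusted p under 0.05, 541 without transgenic replicate 4). The number of lists shifted, 5, was 2 with the filter on the mean, 2 with quantile normalization, 1 with median centring, 11 with array weights, 2 without _x_at and _s_at probe sets, 3 with camera on ranks, 0 with fry, 0 with an estimated correlation, 0 with an estimated correlation without transgenic replicate 2 and 0 with one without transgenic replicates 2 and 3. It ranged from 0 to 10 when each array was left out, with 1 without transgenic replicate 1, 10 without replicate 2, 0 without replicate 3 and 1 without wild-type replicate 3; the cause was not tested. The matrix list was lower in all 24 alternatives by the test's direction and was called in 19 of them. Fatty acid oxidation turned to lower without transgenic replicates 2 and 3 (median 0.017, limma camera adjusted p = 0.980; 0.986 with an estimated correlation). Of the 5 lists called, 62 of 120 values in alternatives lost the call, and of the 24 others, 27 values gained one. The direction of the test turned in 2 values of the 5 lists called with all 8 arrays, both of fatty acid oxidation, and in 58 values of 16 of the 24 lists not called, and 0 of the turned values were called. Of 3054 values of named genes in alternatives, 63 moved by more than the spread between mice and 1 passed the threshold. Hey2 lay between -0.30 and 0.12 over 21 alternatives, and the filter above 7 left it out. The labels number the replicates alike in both groups but do not state that the numbers pair mice, so they were not taken to do so. Deviations from the group means correlated across genes at r = 0.30, -0.01, -0.33 and 0.20 for numbers 1 to 4. Transgenic replicates 1 and 4 correlated best with wild-type replicates 1 and 4, and transgenic replicates 2 and 3 with wild-type replicates 3 and 2. Since transgenic replicates 2 and 3 stood apart and shaped these deviations, the values do not decide whether mice were paired. The replicate block gave 0 genes higher, 0 lower (limma, 147 at an unadjusted p under 0.05) and 1 list shifted. Values near the lower end of the scale are limited by the background correction.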

Other observations

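The test of the atrial genes was chosen only after the result was seen, and the genes named for single arrays were chosen after their values were seen, by their distance from the median of the arrays they are set against, with clone identifiers left out. In transgenic replicate 3, set against the 6 arrays other than transgenic replicate 2, the genes furthest below that median were Cthrc1, a secreted protein of injured tissue, at 3.02 against 9.28 to 11.23, and Col11a1, at 2.75 against 8.25 to 10.33. Next came Cilp at 5.70 against 10.11 to 11.54, Serpinb1a, a protease inhibitor, at 5.85 against 10.10 to 12.66, and Pamr1 at 3.99 against 7.93 to 9.06. On the higher side, Cabcoco1 was 8.04 against 4.50 to 6.02, Hspa1b, a heat shock protein, 12.75 against 8.63 to 13.42, Ces1d, a carboxylesterase, 10.87 against 7.47 to 9.23, and Fbp2, the muscle fructose bisphosphatase, 8.10 against 5.33 to 5.91. No enrichment was tested over the genes of single arrays.

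In transgenic replicate 2, set against the other 7 arrays, the genes furthest below the median were Esf1, at 3.08 against 8.95 to 9.22, Pggt1b, at 2.62 against 8.07 to 8.55, and Exoc5, of the exocyst, at 3.46 against 8.44 to 8.97. The genes furthest above it were Tap1, the peptide transporter of antigen processing, at 8.14 against 4.55 to 6.22, Irgm2, an immunity-related GTPase, at 10.12 against 6.75 to 8.49, Tnfaip8l1, at 8.11 against 5.33 to 6.45, and Col8a2, a chain of type VIII collagen, at 7.25 against 2.22 to 6.35.

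Myl7, Myl4, Sln and Stard10, members of the atrial list, differed by 0.71, 0.67, 0.64 and 0.63 between arrays labelled transgenic and wild type, and Hey1 by 0.59, none of them past the limma threshold. As a hypothesis, these values may be part of a shift of atrial myocyte genes. The 13 members of the atrial list other than Myl7 had no shift past the threshold as a group (limma camera, p = 0.874; mean difference 0.09, exact two-sided permutation p = 0.543), and they went both ways. Nppa, Dkk3 and Clu differed by -0.44, -0.47 and -0.40, with transgenic replicate 3 at -2.03, -1.14 and -1.85 from the wild-type mean. That array also lay high for Myl7, Myl4, Sln and Stard10, at 1.09, 0.46, 0.86 and 1.18. Without transgenic replicates 2 and 3, Myl7, Myl4 and Stard10 differed by 0.48, 0.49 and 0.20, Nppa by 0.13 and Dkk3 by -0.38. Members on both sides thus depended on single arrays, and the hypothesis stays open.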
